A study of Homo sapiens with 6 samples.

How the data were processed

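RNA from MCF7 cells was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, on which a gene is read by 1 or more probe sets. Per the labels' protocols, cells were transfected with 5 nM siRNA using a lipid reagent and harvested after 24 h, and biotin-labelled cRNA was made from total RNA. The 6 arrays form 2 groups of 3: cells given a control siRNA and cells given an siRNA against ESR1, the gene of estrogen receptor alpha. Groups were taken from the labels. The labels name no batch, pairing or siRNA sequence, and arrays are numbered here only to name them. Sample titles hold a code that differs for every array and end in a number, 14.1, 57.1 and 97.1 for control arrays 1, 2 and 3 and 7.1, 8.1 and 9.1 for the ESR1 siRNA arrays, whose meaning is not given in the sources used here. The labels do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

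The deposited values are log2 expression values per probe set, made with RMA (background correction, normalization between arrays and summary per probe set) per the submitters' processing notes. The RMA software, its version and the set of arrays normalized together are not given in the sources used here. The array medians lay between 5.16 and 5.19 on the log2 scale and the values ran from 2.11 to 14.77. RMA compresses differences near background, so fold changes of dim probe sets are likely to be understated. The table holds no detection calls, so a low value was not read as absence. The number of arrays limits the precision of every comparison. Other columns of per-sample values numbered 0.

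The table had 54675 probe sets. The 62 AFFX control probe sets were left out of the tests, leaving 54613. Names came from the platform annotation supplied with the table: 41091 probe sets had 1 symbol, 1801 had several and were not named, and 11721 were not listed and stayed unnamed here. Of the single-symbol probe sets, 41037 matched a RefSeq gene table of assembly GRCh38.p14 and 54 did not. That table was used only for names and for the neighbours of ESR1, and no coordinates are printed because the sources name no genome build. For counts of genes, each of 19775 symbols was represented by the probe set with the highest mean over all 6 arrays.

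Differences were fitted as ESR1 siRNA minus control siRNA with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on dim probe sets), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets or over all genes. A change was called at an adjusted p under 0.05. Fold changes are printed on the log2 scale with their standard error (SE). Single values per array, such as control-probe means, were compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 arrays against 3.

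A set of 18 gene lists with 443 symbols was fixed from textbook knowledge. They covered estrogen-induced and estrogen-repressed genes, G1/S and replication, G2/M and mitosis, ribosome biogenesis, p53 targets, the BCL2 family, nuclear receptors and coregulators, growth factor signalling, luminal, basal/myoepithelial and mesenchymal markers, markers of other cell types, interferon-stimulated genes, unfolded protein and integrated stress responses, cholesterol synthesis, hypoxia and glycolysis, and neighbours of ESR1. Of these symbols 408 were measured by a probe set of their own and 35 were not. Each list was tested against all other genes with camera from limma (preset correlation 0.01, adjusted over the 18 lists), and members were counted after adjustment over all genes and adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were alternatives.

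The text names ESR1, the 10 largest falls and the 10 largest rises among genes past the threshold with a group mean of at least 6 in the higher group and no overlap between groups (symbols starting LOC, FLJ, KIAA or MGC and open reading frame names left out), and from each list up to 4 members past the threshold with the largest change, or the 2 brightest where none passed. This rule gave 57 genes. Any other gene named was chosen after its values were seen, which is said of it or holds for list members given as further examples. The tests described so far, the 18 lists, the naming rule and the alternatives other than those with the spike-in level were chosen before the data were examined. Checks of the G2/M list and of the ESR1 probe sets, and 5 further gene groups, were chosen afterwards.

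The means of the 24 poly-A spike-in probe sets (control RNA that Affymetrix protocols add before labelling), of the 18 hybridisation control probe sets and the 3' minus 5' signal of ACTB and GAPDH were computed for each array. After the data were seen, the spike-in level was added as a technical batch: arrays were parted at the first gap over 0.3 in the sorted log2 means. Control array 1 and all 3 ESR1 siRNA arrays lay below that gap, and control arrays 2 and 3 above it. The end numbers of the titles part the arrays in the same way. Control arrays 2 and 3, at 8.19 and 7.77, also lay more than 0.3 apart but were kept as 1 level. With this level as a term, the estimated difference is that between the ESR1 siRNA arrays and control array 1. Control array 1, the only control at that level, is then fitted exactly. The spread comes from the ESR1 siRNA arrays and from control arrays 2 and 3. SEs and p-values of that fit thus hold no measure of how variable such a control is. No ESR1 siRNA array lay above the gap, so no difference can be given there.

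The fits were tested on simulated data in which 200 features were changed, in 20 simulations with variances drawn from the fitted prior. For genes, 56.5% of changes of 0.5 on the log2 scale, 98.7% of changes of 1 and 100% of changes of 2 were recovered, and 4.85% of calls were false. For probe sets the recovered shares were 23.9%, 95.8% and 100%, with 5.56% false. The variances of the real features after shrinkage by eBayes, which are less spread than the raw ones, were used instead in a further run. The recovered shares were then 84.6%, 100% and 100% for genes and 58.2%, 99.5% and 100% for probe sets. Of gene calls 6.57% and of probe set calls 8.39% were false. The G1/S list, shifted by 0.3, was called in 20 of 20 simulations, and with no list shifted a mean of 0.05 lists was called per simulation. Smaller shifts, such as the size of that list's real mean difference of -0.16, were not simulated. The noise of each feature was drawn independently in all simulations. They therefore could not test the list calls where members vary together, and the estimated correlation within the real lists reached 0.93. Alternatives were quantile normalization again, centring on the median or the 75th percentile, an intensity trend with robust hyperparameters, array weights, filters on dim probe sets, other choices of a gene's probe set, each array left out in turn, list members held by 1 list only, and the spike-in level as a term or the spike-in mean as a covariate.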

Results

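The series measured gene expression in MCF7, a human breast cancer cell line that expresses estrogen receptor alpha and whose growth responds to estrogen. The 6 arrays came from 3 samples transfected with a control siRNA and 3 transfected with an siRNA against ESR1, all harvested after 24 h. The labels name no estrogen added to or withdrawn from the serum-containing medium. Values are deposited log2 RMA expression. Over all probe sets, Pearson's r was 0.9949 to 0.9956 between control arrays, 0.9964 to 0.9965 between ESR1 siRNA arrays and 0.9936 to 0.9953 between arrays of different groups. The poly-A spike-in probe sets had a mean log2 signal of 7.28, 8.19 and 7.77 in control arrays 1, 2 and 3, and of 7.38, 7.35 and 7.22 in the ESR1 siRNA arrays. Their group means were 7.75 ± 0.45 and 7.32 ± 0.08 (SD, n = 3 each, exact permutation p = 0.3). The hybridisation controls (10.87 ± 0.13 against 10.63 ± 0.31, exact p = 0.3), the 3' minus 5' signal of ACTB (1.23 ± 0.10 against 1.09 ± 0.15, exact p = 0.3) and that of GAPDH (0.35 ± 0.05 against 0.31 ± 0.04, exact p = 0.5) also overlapped between groups. For 3 arrays against 3 the smallest possible exact p is 0.1.

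The ESR1 transcript itself was measured first. Its brightest probe set read 10.72 ± 0.11 in the control arrays and 8.50 ± 0.11 in the ESR1 siRNA arrays (SD, n = 3 each), so that 21.4% of the control signal remained. ESR1 fell by 2.22 on the log2 scale (SE 0.10, a 4.67-fold change, limma adjusted p = 1.53e-05 over probe sets). With the spike-in level as a term the difference was -2.35 (adjusted p = 5.10e-04). The other 8 probe sets of ESR1 did not pass the threshold. The largest difference among them was -0.68 (SE 0.15, adjusted p = 0.0855), in a probe set that read 5.11 ± 0.18 in controls. The next 3 by brightness, between percentiles 69.6 and 73.9 of all probe sets, differed by -0.10, -0.20 and -0.14. The mean of all its probe sets differed by -0.37 (adjusted p = 0.0218). The labels do not give the siRNA's target site, so it is not known which probe sets lie beside it.

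**Figure D1:**
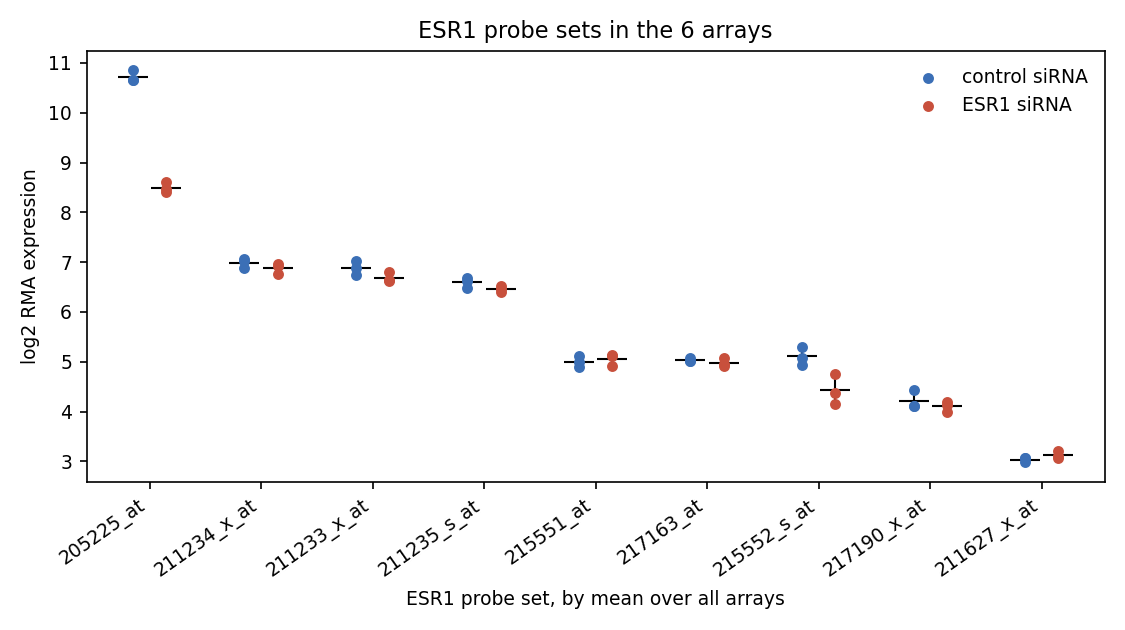
Log2 RMA expression (vertical axis) of the 9 ESR1 probe sets, ordered by mean signal, with 1 point per array, horizontal lines at group means and vertical lines for 1 SD. The brightest probe set lies near 10.72 in the 3 control arrays and near 8.50 in the 3 ESR1 siRNA arrays, while the groups lie within 0.20 of each other for 7 of the other 8 probe sets.

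Which transcripts differ after ESR1 siRNA was the question of the single comparison. The labels tell no different ESR1 siRNAs apart, so other effects of the siRNA cannot be separated from the loss of ESR1. The largest falls beside ESR1 were in ATRNL1, an attractin-like gene that went from 7.02 ± 0.22 to 4.35 ± 0.18 (SD, n = 3 each; log2 fold change -2.67, SE 0.13, limma adjusted p = 5.54e-06), and in RASGRP1, an exchange factor that activates Ras (-2.15, SE 0.09, adjusted p = 3.12e-06). CXCL12, a secreted chemokine, fell by 1.80 on the log2 scale (SE 0.10, adjusted p = 2.02e-05). The secreted glycoprotein gene STC2 (log2 fold change -1.75, SE 0.10) and the transcription factor MYC, which went from 9.78 ± 0.11 to 8.08 ± 0.07 (-1.69, SE 0.09, adjusted p = 1.06e-05), also fell. The phosphoesterase gene MPPED2, the RNA-binding protein gene RBM24, the cadherin CDH26 and the transglutaminase TGM2 completed the 10 largest falls, with log2 fold changes of -1.72, -1.57, -1.57 and -1.56. The largest rises were in TP53INP1, a p53-inducible regulator of autophagy and cell death (1.49, SE 0.16, adjusted p = 0.00110), CCDC68 (1.30, SE 0.11) and ACLY, which makes cytosolic acetyl-CoA (9.69 ± 0.19 to 10.99 ± 0.05; 1.30, SE 0.10, adjusted p = 1.55e-04). Next came TMEM87B (1.23), the iron transporter SLC11A2 (1.23) and TMEM65 (1.17). The mitotic kinase NEK7, the cancer/testis transcript CT75, the kinetochore protein CENPK and PRR11 followed with 1.14, 1.12, 1.12 and 1.08.

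Of 19775 genes, 427 changed, 160 upward and 267 downward, by limma at an adjusted p under 0.05. In each of the 427 genes the 3 ESR1 siRNA arrays lay on one side of the 3 control arrays. Such a separation held for 19.3% of all genes, where chance gives 10%. At least 2-fold changes were seen in 53 genes, 14 higher and 39 lower. At the level of probe sets, 510 of 54613 changed, 173 upward and 337 downward. Of the 288 changed genes with more than 1 probe set, 67 had a second that passed in the same direction and 0 had 1 that passed in the opposite direction. With the spike-in level as a term 155 genes changed (58 higher, 97 lower), 125 of them among the 427, and 53 changed at least 2-fold. The count was 713 without control array 1, 225 without control array 2, 303 without control array 3, and 219, 191 and 181 without ESR1 siRNA array 1, 2 and 3. TGM2 and PRR11 were the 2 of these 20 genes that lost their call with the spike-in level (log2 fold change -0.70, adjusted p = 0.276, and 0.47, adjusted p = 0.177). Both also lost it without control array 2 or any ESR1 siRNA array, and PRR11 without control array 3, and both with an intensity trend (adjusted p = 0.192 and 0.174). ATRNL1 was represented by another probe set without control array 1, 2 or 3 and fell by less there (log2 fold change -1.29, -1.30 and -1.25). With the mean of all probe sets of a gene, the differences were smaller by more than 1.5 times for ATRNL1 (-1.33), MPPED2 (-1.02), CDH26 (-0.78), TGM2 (-0.51), TP53INP1 (0.47), SLC11A2 (0.52), CT75 (0.68) and PRR11 (0.57), and TGM2 and PRR11 did not pass. With probe sets lacking an _x_at or _s_at ending preferred, SLC11A2 was represented by another probe set with a difference of 0.12 (adjusted p = 0.660).

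**Figure D2:**
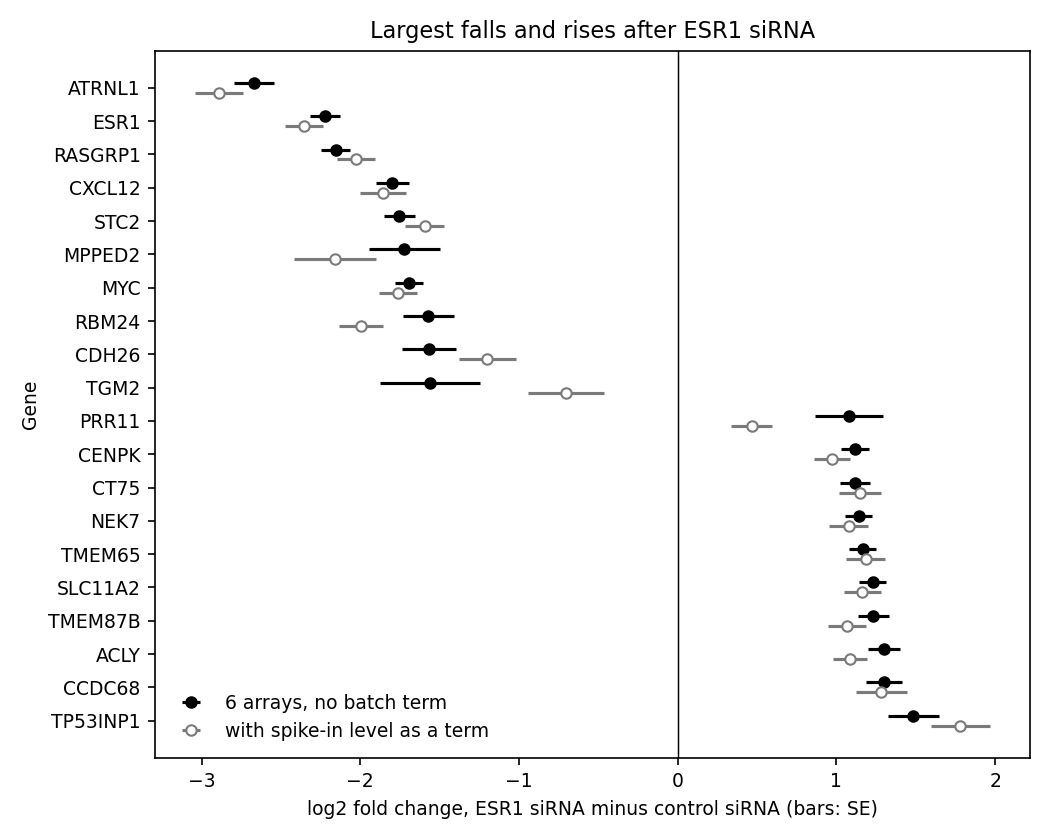
Log2 fold change (horizontal axis, ESR1 siRNA minus control siRNA; bars are 1 SE) of the 10 largest falls and 10 largest rises, without a batch term (filled) and with the spike-in level as a term (open). TGM2 moves from -1.56 to -0.70 and PRR11 from 1.08 to 0.47, and the other 18 genes stay past the threshold in both fits.

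Genes known to be induced by estradiol fell together. Of 57 measured members of that list, 30 fell and 0 rose by limma over all genes, and 46 fell when adjusted over the list alone. At an unadjusted p under 0.05, 46 were lower and 0 higher. Beside CXCL12, STC2 and MYC, the list held PDZK1, a scaffold protein of membrane transporters (-1.46, SE 0.24, adjusted p = 0.0124), and PGR, the progesterone receptor (7.23 ± 0.23 to 5.83 ± 0.16; -1.40, SE 0.12, adjusted p = 2.87e-04). Further members chosen as examples after their values were seen were GREB1 (-1.17, SE 0.15), the carbonic anhydrase CA12 (-0.98, SE 0.09) and the G1 cyclin CCND1 (11.39 ± 0.03 to 10.63 ± 0.09; -0.76, SE 0.08). Classical members without a change past the threshold over all genes included TFF1 (0.03, SE 0.09, adjusted p = 0.919), TFF3 (-0.27), CTSD (-0.28) and BCL2 (0.04, SE 0.17). TFF1 read 14.19 and 14.22, near the array maxima of 14.58 to 14.77, where a fall could be hidden, and differed by -0.12 with the spike-in level. BCL2, with an SD of 0.42 among controls, differed by 0.50 (SE 0.13, adjusted p = 0.127) with that level. The mean difference of the 57 genes was -0.59, and the list stood lower than other genes (camera adjusted p = 2.32e-41; adjusted p = 0.0126 with an estimated correlation). With the spike-in level as a term 23 members fell and the mean was -0.65 (adjusted p = 2.23e-39). PDZK1 lost its call without ESR1 siRNA array 1 (adjusted p = 0.0790) and with an intensity trend (0.0541).

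Genes known to be repressed by estradiol were higher as a list. Of 23 measured members 2 rose, TP53INP1 and CCNG2, an unconventional cyclin linked to cell cycle arrest (7.89 ± 0.16 to 8.92 ± 0.10; 1.02, SE 0.10, adjusted p = 5.10e-04; 0.67 with the mean of all its probe sets). By limma 0 fell, with 2 lower and 9 higher at an unadjusted p under 0.05. Adjusted over the list alone, 5 rose; the further 3 were ERBB3, PSCA and CYP1A1, with differences of 0.40, 0.54 and 0.49 (0.60, 0.62 and 0.77 with the spike-in level). The mean difference was 0.23 and 17 of 23 members were higher (camera adjusted p = 3.56e-04; adjusted p = 0.359 with an estimated correlation). With the spike-in level as a term the mean was 0.33 (adjusted p = 4.6e-07).

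The list of ribosome biogenesis genes and MYC targets, which also holds the polyamine synthesis genes ODC1 and SRM, was lower in all 19 measured members. Of these 8 fell and 0 rose over all genes, and 15 fell when adjusted over the list alone. At an unadjusted p under 0.05, 15 were lower and 0 higher. NOP16 (-0.69, SE 0.08, adjusted p = 0.00119), NOLC1 (-0.63, SE 0.09), RRP12 (-0.61, SE 0.08) and POLR1B, a subunit of RNA polymerase I (-0.48, SE 0.09, adjusted p = 0.0272), fell. The mean difference was -0.37 (camera adjusted p = 2.98e-17; adjusted p = 0.0728 with an estimated correlation), and -0.44 with the spike-in level as a term (adjusted p = 1.60e-17), when NOP16 and RRP12 stayed past the threshold. Another probe set of RRP12, without an _x_at or _s_at ending, differed by -0.01. The mean of all probe sets was -0.15 for RRP12, -0.33 for NOP16 and -0.32 for POLR1B, and none of the 3 passed (adjusted p = 0.347, 0.0762 and 0.0794). When the spike-in level was a term, NOLC1 (-0.54, SE 0.12) and POLR1B (-0.59, SE 0.12) lost their calls with a larger SE, and POLR1B also without control array 2 or ESR1 siRNA array 1 or 2, with its probe set of largest variance, and with probe sets lacking an _x_at or _s_at ending preferred.

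Genes of the G1/S transition and DNA replication were lower by a small amount. Of 40 measured members 2 fell and 1 rose: the transcription factor E2F2 (-0.53, SE 0.10, adjusted p = 0.0203) and cyclin E1, CCNE1 (-0.52, SE 0.11, adjusted p = 0.0473), fell, and RFC5, a subunit of the replication clamp loader, rose (0.44, SE 0.08, adjusted p = 0.0156). Adjusted over the list alone, 17 fell and 2 rose. MCM3 and MCM5, subunits of the replicative helicase, differed by -0.36 and -0.35. The mean difference was -0.16 with 32 of 40 members lower (camera adjusted p = 1.65e-09; adjusted p = 0.134 with an estimated correlation), and -0.16 with the spike-in level as a term (adjusted p = 1.37e-07). E2F2, CCNE1 and RFC5 each lost their call with the spike-in level (-0.38, -0.25 and 0.39, SE 0.12, 0.11 and 0.11) and without any 1 array other than control array 1. The mean of all probe sets was -0.20 for E2F2, -0.15 for CCNE1, whose second, dim probe set differed by 0.23, and 0.30 for RFC5, and none of them passed. CCNE1 kept the same difference but lost its call with the probe set of largest variance for each gene (adjusted p = 0.0803). It also lost its call after quantile normalization and after centring on the 75th percentile.

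G2/M and mitosis genes differed among the control arrays by more than between the groups. Of 34 measured members 33 were higher in the mean of the ESR1 siRNA arrays, and 1 rose, the survivin gene BIRC5 (9.86 ± 0.06 to 10.22 ± 0.03; 0.36, SE 0.08, adjusted p = 0.0435). By limma 0 fell, with 0 lower and 17 higher at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone. The mitotic kinase PLK1 differed by 0.72 (SE 0.28), the kinesin KIF20A by 0.78 (SE 0.32) and cyclin B1, CCNB1, by 0.51 (SE 0.19), each short of the threshold, and by -0.11, -0.22 and -0.05 with the spike-in level. Relative to the control mean, the list stood at 0.54, -0.21 and -0.33 in control arrays 1, 2 and 3 and at 0.37, 0.42 and 0.47 in the ESR1 siRNA arrays. Control array 1 had a poly-A spike-in level near that of the ESR1 siRNA arrays (7.28 against 7.38, 7.35 and 7.22). The mean difference was 0.42 (camera adjusted p = 6.92e-11; adjusted p = 0.471 with an estimated correlation; exact permutation p of the list mean = 0.4). It was -0.12 (SE 0.07) with the spike-in level as a term, a difference from control array 1 alone. It was 0.69 without control array 1, 0.32 without control array 2 and 0.26 without control array 3. BIRC5 lost its call with the spike-in level (0.31, SE 0.11), without any 1 array other than control array 1, and with each other choice of probe set (0.34 to 0.47, adjusted p = 0.0503 to 0.358). The adjusted p of 0.0503 belongs to the same difference of 0.36, with probe sets lacking an _x_at or _s_at ending preferred.

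Regulators of apoptosis moved in single genes. PMAIP1, which encodes the BH3-only protein NOXA, fell from 7.56 ± 0.19 to 6.53 ± 0.25 (-1.02, SE 0.13, adjusted p = 0.00383), and HRK, another BH3-only gene with a dim signal, rose from 4.85 ± 0.12 to 5.41 ± 0.09 (0.56, SE 0.09, adjusted p = 0.0113). The other 12 of 14 measured BCL2 family genes did not pass, the same 1 rise and 1 fall passed when adjusted over the list alone, and the list did not stand apart (mean 0.02, camera adjusted p = 0.392). Of 21 measured p53 targets TP53INP1 rose, while AEN, an apoptosis-enhancing nuclease, and the death receptor FAS fell (-0.60, SE 0.08, adjusted p = 0.00313, and -0.57, SE 0.08, adjusted p = 0.00405). The other 18 did not pass, with CDKN1A, which encodes the cell cycle inhibitor p21, at -0.03 (SE 0.09). Adjusted over the list alone, 1 rose and 5 fell, and the list mean was -0.03 (camera adjusted p = 0.160). HRK turned to -0.24 (adjusted p = 0.462) with probe sets lacking an _x_at or _s_at ending preferred, was 0.07 (adjusted p = 0.789) with the mean of all its probe sets, and lost its call without ESR1 siRNA array 2. FAS lost its call with the former choice of probe set (-0.14) but not with that of largest variance (-0.90), and AEN (-0.58, SE 0.11, adjusted p = 0.0505) and FAS (-0.55, SE 0.11) lost theirs with the spike-in level, where the SE was larger.

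Among nuclear receptors and coregulators, PGR and the corepressor NRIP1 (-0.58, SE 0.09, adjusted p = 0.0109) fell, and the membrane estrogen receptor gene GPER1 (0.51, SE 0.09, adjusted p = 0.0163) and the coactivator NCOA2 (0.49, SE 0.10, adjusted p = 0.0395) rose. The other 19 of 23 measured members did not pass, 3 rose and 3 fell when adjusted over the list alone, and the list had a mean of -0.01, a median of 0.09 and an upward camera test (adjusted p = 0.541). Among 29 measured growth factor genes 3 fell: the IGF-binding protein IGFBP4 (9.27 ± 0.27 to 8.23 ± 0.13; -1.04, SE 0.13, adjusted p = 0.00281), the GDNF family receptor GFRA1 (-0.77, SE 0.11, adjusted p = 0.00736) and the receptor IGF1R (-0.49, SE 0.09, adjusted p = 0.0171). By limma 0 of them rose, with 2 higher and 7 lower at an unadjusted p under 0.05; adjusted over the list alone, 4 fell and 1, ERBB3, rose. The list's mean was -0.11 (camera adjusted p = 0.0478; adjusted p = 0.359 with an estimated correlation; mean -0.05 and adjusted p = 0.628 with the spike-in level as a term; 0.365 without control array 3). NRIP1 (-0.61, SE 0.13), GPER1 (0.37, SE 0.11), NCOA2 (0.40, SE 0.14) and IGF1R (-0.60, SE 0.11) lost their calls with the spike-in level, NRIP1 and IGF1R with a larger fall and a larger SE. GPER1, NCOA2 and IGF1R also lost them without any 1 of the ESR1 siRNA arrays, GPER1 and NCOA2 without control array 2, and NCOA2 without control array 3. With the probe set of largest variance for each gene NRIP1 (-0.34), GPER1 (0.43) and IGF1R (-0.19) did not pass (adjusted p = 0.679, 0.275 and 0.862). NCOA2 kept the same difference there (0.49) but did not pass either (adjusted p = 0.0744). With the mean of all probe sets NRIP1 (-0.46), NCOA2 (0.31) and IGF1R (-0.33) did not pass (0.252, 0.0608 and 0.117).

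Markers of cell identity showed few changes. In the luminal list 1 of 21 measured members fell, the transcription factor XBP1, itself an estrogen-induced gene (12.69 ± 0.09 to 12.24 ± 0.01; -0.45, SE 0.08, adjusted p = 0.0179). In it 0 rose by limma (3 higher and 2 lower at an unadjusted p under 0.05), and the luminal factors GATA3 and FOXA1 differed by 0.09 and 0.11 (SE 0.08 each). The same gene alone passed when adjusted over the list alone, and the list mean was -0.03 (camera adjusted p = 0.505). In the basal/myoepithelial list 2 of 17 fell and 0 rose, with 6 lower and 0 higher at an unadjusted p under 0.05: the caveolin CAV1 (-0.72, SE 0.11, adjusted p = 0.00956) and the integrin ITGA6 (-0.49, SE 0.10, adjusted p = 0.0354), which also passed when adjusted over the list alone. The basal keratins KRT5 and KRT14 differed by -0.01 and -0.03, and the list mean was -0.17 (camera adjusted p = 0.00148; adjusted p = 0.135 with an estimated correlation; mean -0.13 and adjusted p = 0.0969 with the spike-in level as a term). Of 14 mesenchymal genes 0 passed by limma over all genes (4 at an unadjusted p under 0.05) and 2, SNAI2 and FN1, fell when adjusted over the list alone. The fibronectin gene FN1 differed by -0.44 (SE 0.12) and TGFBI by -0.27 (SE 0.14), and the list mean was -0.04 with a median of 0.03 (camera adjusted p = 0.733). Of 16 markers of other cell types, whose list mean was 4.85 ± 0.05 in controls and 4.79 ± 0.03 after ESR1 siRNA, 0 passed over all genes (1 at an unadjusted p under 0.05). LUM, with a dim signal of 3.45 and 2.89, alone fell when adjusted over the list alone (-0.56, SE 0.13; -0.28 with the spike-in level, adjusted p = 0.516), and COL1A1 and HBB differed by 0.05 and 0.08 (camera adjusted p = 0.366). COL1A1 differed by 0.91 (adjusted p = 0.0899) with its probe set of largest variance and by 0.38 (adjusted p = 0.115) with the mean of all its probe sets. The 6 measured neighbours of ESR1 held 0 changes by limma, also at an unadjusted p under 0.05 and when adjusted over the list alone, with RMND1 at 0.03, CCDC170 at -0.19 and a list mean of 0.02 (camera adjusted p = 0.759). XBP1 (-0.50, SE 0.11), CAV1 (-0.81, SE 0.16) and ITGA6 (-0.47, SE 0.14) lost their calls with the spike-in level, where the SE was larger, and the mean of all probe sets of XBP1 was -0.09, its second, dim probe set differing by 0.27. These 3 genes also lost their calls without ESR1 siRNA array 1, XBP1 and ITGA6 without ESR1 siRNA array 2 or 3, XBP1 without control array 2 and ITGA6 without control array 3. With the probe set of largest variance for each gene, XBP1 and ITGA6 kept the same differences but lost their calls (adjusted p = 0.0532 and 0.0687). ITGA6 also lost its call with the mean of all its probe sets (-0.38, adjusted p = 0.161). TGFBI passed without control array 1 (-0.46, adjusted p = 0.0167), and was 0.11 with the spike-in level. FN1 passed with an intensity trend (adjusted p = 0.0463) and with array weights (0.0472), and was -0.02 with probe sets lacking an _x_at or _s_at ending preferred and -0.27 with the spike-in level.

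Stress and metabolic lists changed little. Of 34 interferon-stimulated genes, which transfected RNA can induce, 1 rose, IFITM1 (0.41, SE 0.08, adjusted p = 0.0350), also when adjusted over the list alone, and 0 fell by limma (2 higher and 3 lower at an unadjusted p under 0.05), with a list mean of -0.07 (camera adjusted p = 0.198). Genes of the unfolded protein and integrated stress responses held 0 of 24 changes by limma over all genes or over the list alone (5 lower at an unadjusted p under 0.05), with the chaperone HSPA5 at -0.22 (SE 0.08), the disulfide isomerase PDIA6 at -0.15 (SE 0.08) and a list mean of -0.07 (camera adjusted p = 0.05003). Of 18 cholesterol synthesis genes 0 passed over all genes (2 higher at an unadjusted p under 0.05) and INSIG1 rose when adjusted over the list alone (0.43, SE 0.10; 0.24 with the spike-in level, adjusted p = 0.499). SQLE and FDPS differed by 0.03 and 0.08, and the list mean was 0.10 (camera adjusted p = 0.0490; adjusted p = 0.503 with an estimated correlation; mean 0.01 and adjusted p = 0.971 with the spike-in level as a term; 0.208 without control array 2, 0.167 without control array 3, and 0.0594 and 0.0806 without ESR1 siRNA array 1 and 2). Of 19 hypoxia and glycolysis genes 0 passed over all genes or over the list alone (4 at an unadjusted p under 0.05), with ALDOA at 0.03, LDHA at 0.02 and a list mean of 0.00 (camera adjusted p = 0.796). IFITM1 lost its call with the spike-in level (0.30, SE 0.11), without any 1 array other than control array 1, and with the probe set of largest variance for each gene (adjusted p = 0.0846). HSPA5 passed with an intensity trend (adjusted p = 0.0295) and was -0.44 (adjusted p = 0.161) with its probe set of largest variance. The interferon list passed without control array 1 (adjusted p = 0.0200), and the stress list without control array 2 (0.0457) or ESR1 siRNA array 1 or 2 (0.0449 and 0.0387).

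**Figure D3:**
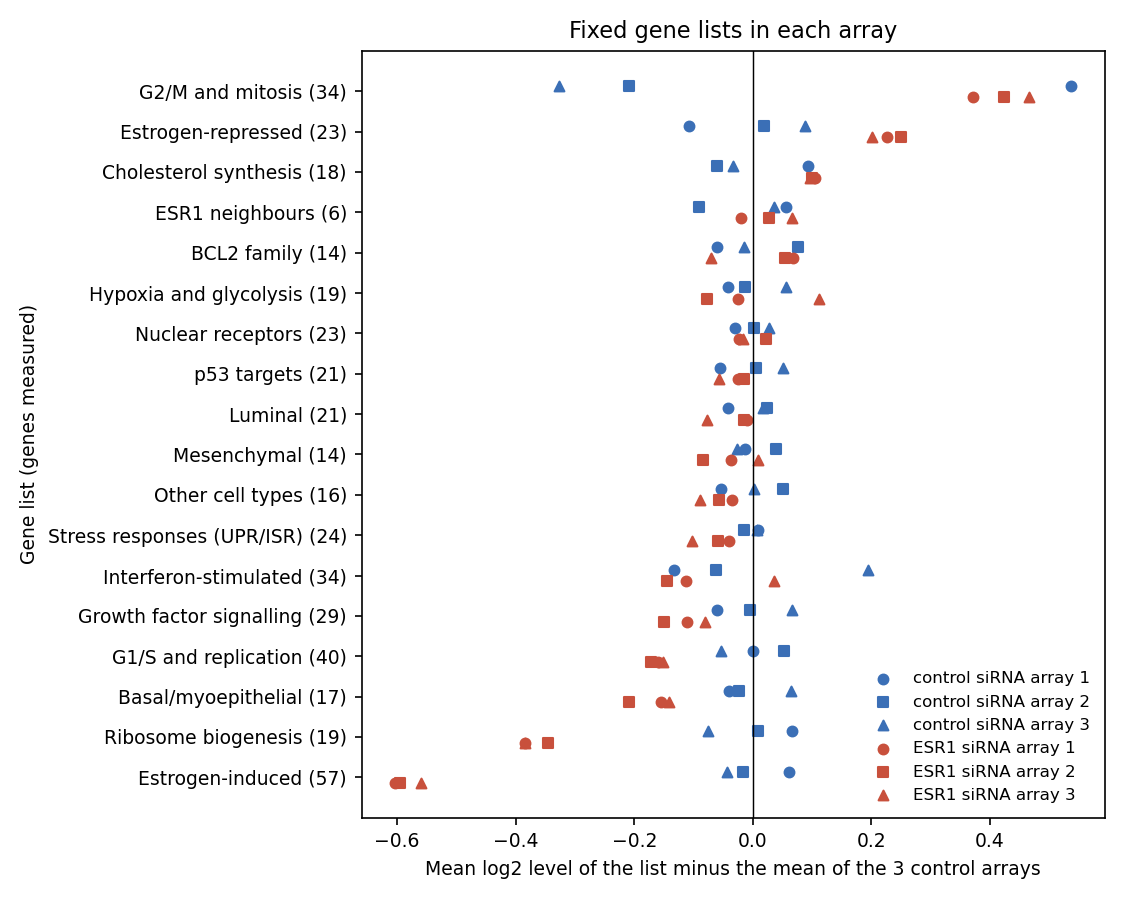
Mean log2 level of the measured genes of each fixed list in each array, minus the mean of the 3 control arrays (horizontal axis), with the number of genes in brackets and a line at 0. The ESR1 siRNA arrays lie apart from the controls for estrogen-induced genes (mean difference -0.59) and ribosome biogenesis (-0.37). With smaller differences they also do so for estrogen-repressed (0.23), basal/myoepithelial (-0.17), G1/S (-0.16), growth factor (-0.11), cholesterol synthesis (0.10) and stress response (-0.07) genes. For G2/M and mitosis control array 1 (0.54) lies above all ESR1 siRNA arrays (0.37 to 0.47).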

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

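The alternatives with the spike-in level as a term or the spike-in mean as a covariate were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers shared by the groups. ESR1 stayed past the threshold in each setting, with leave-one-out values from -2.28 to -2.16. Of the 45 named genes past the threshold 22 stayed past it under each of 18 settings, and 1 reversed, HRK (-0.24 with probe sets lacking _x_at or _s_at endings first, where another probe set stands for the gene). The number of genes changed, 427, became 660 with an intensity trend and robust hyperparameters, 681 with array weights, 155 with the spike-in level as a term and 172 with the spike-in covariate, and lay between 181 and 713 when 1 array was left out. The number of probe sets changed, 510, became 890, 144 and 166 with the trend, the spike-in level and the spike-in covariate, and lay between 187 and 695 with 1 array left out. The number changed at least 2-fold, 53, became 30 with the mean of all probe sets of a gene and lay between 45 and 63 with 1 array left out. Quantile normalization and centring on the median or the 75th percentile gave 430, 432 and 404 genes.

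Lists were judged by their adjusted p. With an estimated correlation the lists past the threshold, other than the estrogen-induced one, rose to 0.359 (estrogen-repressed), 0.134 (G1/S), 0.471 (G2/M), 0.135 (basal), 0.503 (cholesterol synthesis), 0.0728 (ribosome biogenesis) and 0.359 (growth factors). The correlation estimated for the basal list was 0.02, near the preset 0.01. Its rise thus cannot be read as an effect of correlation alone. Fry gave 0.0993 for estrogen-repressed genes, 0.325 for G2/M, 0.267 for cholesterol synthesis and 0.116 for growth factors. With the spike-in level as a term G2/M genes reversed to a mean of -0.12 (0.00154), the cholesterol list lost its call with the direction of its test reversed at a mean of 0.01 (0.971), and basal (0.0969) and growth factor genes (0.628) lost their calls; with the spike-in covariate G2/M (0.555), cholesterol (0.83) and growth factor genes (0.240) did. The G2/M value with the spike-in level rests on the preset correlation of 0.01. The correlation estimated for this list without that term was 0.93. Control array 1 is the only control in that fit's difference, and the list mean differed from it by -0.12 (SE 0.07). The fit holds no measure of how variable such a control is, so a reversed effect cannot be concluded from it. Cholesterol synthesis gave 0.0766 and 0.0796 with the filters at a mean of at least 5 and above the median, and 0.0700 with probe sets lacking _x_at or _s_at endings first. Growth factors gave 0.0919, 0.0965 and 0.129 with the same choices, 0.101 with the probe set of largest variance and 0.0506 with the mean of all probe sets. With members of 1 list only, p53 targets (0.0301) and stress responses (0.045) passed the threshold, and stress responses also with the intensity trend (0.0293). That choice leaves out TP53INP1, the 1 p53 target that rose, because the estrogen-repressed list also holds it. The p53 targets still called, AEN and FAS, fell. The cause of these changes was not tested.

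With 1 array left out, the adjusted p ranged from 7.38e-46 to 2.52e-35 for estrogen-induced genes, 1.13e-05 to 0.0125 for estrogen-repressed, 2.80e-11 to 2.02e-06 for G1/S, 1.25e-40 to 2.19e-05 for G2/M, 2.60e-19 to 6.15e-12 for ribosome biogenesis, 0.00130 to 0.00943 for basal, 0.00289 to 0.208 for cholesterol synthesis, 0.00919 to 0.365 for growth factors, 0.0200 to 0.714 for interferon-stimulated genes and 0.0387 to 0.217 for stress responses. The other lists stayed short of the threshold in each such fit. Dim probe sets limit what can be seen, since RMA compresses differences near background and the table holds no detection calls: 28900 of 54613 probe sets had a mean of at least 5.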

Other observations

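The gene groups in this and the next paragraph were put together after the values were seen, so no test of a group as a whole is given. Of 7 measured genes of the ID and BMP response 3 rose by limma: the helix-loop-helix inhibitors ID2 (0.87, SE 0.12, adjusted p = 0.00429) and ID1 (0.64, SE 0.10, adjusted p = 0.00979) and the pseudoreceptor BAMBI (0.48, SE 0.08, adjusted p = 0.0157). With the spike-in level as a term these differed by 0.74, 0.47 and 0.57 and did not pass, and ID3, ID4, SMAD6 and SMAD7 did not pass in either fit. In the aryl hydrocarbon receptor battery 2 of 8 genes rose, the repressor AHRR (0.88, SE 0.12, adjusted p = 0.00541) and AHR itself (0.44, SE 0.09, adjusted p = 0.0307), while the target TIPARP fell (-0.67, SE 0.09, adjusted p = 0.00483). CYP1A1, CYP1B1 and CYP1A2 were higher by 0.49, 0.39 and 0.21 but did not pass by limma (adjusted p = 0.160, 0.0757 and 0.292). NQO1 and ALDH3A1 differed by 0.01 and 0.02. AHR differed by 0.49 with the spike-in level and did not pass (adjusted p = 0.125).

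Among 18 immediate early genes 1 fell, FOS (6.35 ± 0.16 to 5.06 ± 0.19; -1.29, SE 0.11, adjusted p = 2.87e-04), and EGR3 differed by -1.35 (SE 0.31, adjusted p = 0.0600), or by -2.28 (adjusted p = 4.01e-04) with the spike-in level as a term. ACLY was the 1 gene of 10 in fatty acid synthesis that rose, with FASN at 0.15 (SE 0.11) and ACACA at 0.02 (SE 0.09). SCD (0.35, SE 0.12) and SREBF1 (0.26, SE 0.11) were higher but did not pass, and ELOVL6 differed by -0.002. With the spike-in level as a term SCD and SREBF1 differed by 0.10 and 0.08. Of 14 circadian clock genes DBP rose (0.87, SE 0.13, adjusted p = 0.00819), with a difference of 0.67 (adjusted p = 0.130) when the spike-in level was a term.

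The tests on G2/M genes and on ESR1 probe sets below were chosen after those results were seen, and the tests of splits and of scaling before. The first pattern is the higher level of 33 of 34 G2/M and mitosis genes after ESR1 siRNA, with a mean of 0.42. The list's median in control array 1 stood 0.74 above control arrays 2 and 3, where the highest of 10000 random lists of like expression lay at 0.12, but the arrays had been normalized, so this says nothing about an array-wide shift, and a high control array 1 makes the difference smaller (0.69 without it). A batch seen in the poly-A spike-ins and an effect of the knockdown cannot be told apart for these genes, because 1 control array alone lay at the lower spike-in level. The mean of -0.12 (SE 0.07) with that level as a term is the difference from that array, which lay 0.0716 above the highest ESR1 siRNA array, while control arrays 2 and 3 lay below all of them. A difference in growth between cultures was not tested.

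The second pattern is that 8 of 9 ESR1 probe sets did not pass while the brightest fell by 2.22 on the log2 scale. A dim signal from ESR1 itself stays open for all 8. The 3 brighter ones lay above the median of all probe sets, with a largest difference of -0.20, so a low total signal does not account for them. They read 6.60 to 6.99 in controls, against 10.72 for the brightest. How much of that signal comes from ESR1 is not known, so a dim ESR1 signal cannot be told apart from shared sequence. Sequence shared with other transcripts may keep the signal of the 3 up, as all 3 have names ending in _x_at or _s_at, but probe sequences were not analysed here, so this stays open. No biological explanation was tested.

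The third pattern is the larger number of falls than rises, 62.5% of the 427 genes changed. Scaling of the arrays could contribute. The share of falls was 61.4% after quantile normalization and 62.5% after centring on the median. It was 57.4% (binomial SE 2.46 over the called genes) after centring on the 75th percentile. The lowest lay less than 1 SE above the bound of 55% set beforehand. That SE treats genes as independent and does not measure the spread between arrays. With 1 array left out the share ranged from 52.7% to 71.8%. The share was 52.7% without control array 1 and 62.6% with the spike-in level as a term. An effect of ESR1 loss itself stays open and was not tested apart from scaling.

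The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many changed probe sets (510, highest other 9), genes (427, highest other 0, with 444 to 1413 genes at an unadjusted p under 0.05 by limma in the other splits), genes changed at least 2-fold (53, highest other 0) or lists called (8, highest other 6). By the camera p, 1 split was as strong for estrogen-induced genes (1.29e-42, strongest other 2.41e-09), G1/S (3.67e-10, 1.11e-06), ribosome biogenesis (3.31e-18, 2.06e-09) and basal genes (4.93e-04, 0.0197), and 2 splits were for estrogen-repressed (9.89e-05, 2.78e-05) and growth factor genes (0.0186, 0.00551). For cholesterol synthesis (0.0218, 7.39e-04) and G2/M (1.15e-11, 5.06e-31) it was 4 splits, and for G2/M the other 3 put control array 1 with 2 ESR1 siRNA arrays, which follows the spike-in level; with that level as a term the G2/M mean was -0.12.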
